A study of Mus musculus with 2 samples.

How the data were processed

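The series holds 2 anti-FLAG chromatin immunoprecipitation sequencing (ChIP-seq) libraries from C57BL/6 mouse Lin-Sca-1+c-Kit+ cells, a marker combination enriched for haematopoietic stem and progenitor cells. The labels give the tissue as blood and the animals' age as 8 to 10 weeks, and do not give the animals' sex. One library came from cells transduced with a MigR1 retrovirus carrying 3xFLAG-tagged HLF, and the other from cells given the empty vector. Per the labels' protocols, cells were kept in culture for 5 days with SCF at 50 ng/ml, IL-7 and Flt3L at 10 ng/ml each and IL-3 at 5 ng/ml. Libraries were amplified over 15 PCR cycles and sequenced on an Illumina Genome Analyzer. A processed file was used for the FLAG-HLF library. The control library's peaks were not analysed here, so no comparison between the 2 libraries was made.

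The deposited file is a peak list of 3 columns (chromosome, start and end) with no header. Its 3153 intervals are all 400 bp wide, and no line is duplicated. It gives no peak height, fold enrichment, p-value, summit or strand. Bowtie2 2.0.6, MACS2 2.0.10 and the mm10 build are named in the submitters' processing notes, with no role stated for each. The peak threshold, the use of the control library in peak calling and the step that gave every peak one width are not given in the sources used here. Peaks set to one width no longer show how far the enriched region reached, and the interval's centre was used as its position. Read depth is unknown, so the list's sensitivity and the strength of any single peak could not be set. All intervals given below cover counting error over peaks or genes only. There is 1 library and no replicate, so every p-value describes this list against random placement and says nothing of the spread between cultures.

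Gene positions and symbols came from a RefSeq gene table of the GRCm38.p6 assembly, which has the same chromosome coordinates as mm10. It has 49997 rows, of which 49214 were used. The other 783 were 443 on Y, on the mitochondrial genome or without a chromosome, and 340 with a start below 3 Mb on chromosomes 1 to 19 or X. Those 340 carry scaffold coordinates, since each chromosome's own rows begin above 3 Mb. The table gives neither strand nor exons. A gene's 5′ end therefore could not be told from its 3′ end, and exons, introns and UTRs could not be assigned. The planned promoter comparison was run on gene boundaries, meaning either end of a gene. No genome sequence was used, so the planned motif, 8-mer, motif position, GC and repeat comparisons were not run. Without a score column, neither the comparisons by peak score nor the stricter score thresholds could be run.

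Random windows were drawn 1000 times for every peak on the same chromosome, within the span from the first to the last annotated gene or peak. The planned exclusion of assembly gaps was not applied, and sequence where reads cannot be placed was not removed. The windows, and the spans used for peak densities, may therefore include sequence where no peak could be called. Shares were compared by two-sided Fisher's exact test against the 3153000 pooled windows, with Woolf intervals for the odds ratio and exact Clopper-Pearson 95% intervals for shares. Peak densities per chromosome carry exact Poisson 95% intervals. These intervals and the binomial test on X treat peaks as independent, so clustering of peaks would make the intervals too narrow and the p-value too small. For gene lists, a protein-coding gene counted as near a peak when a peak centre lay in its body or within 20 kb on either side. Each of 15 lists was set against 10000 random lists of protein-coding genes matched on the length of that region, in 20 bins on autosomes and 5 on X. The p-value is the share of random lists with as many genes near peaks (one-sided permutation), with Benjamini-Hochberg adjustment over the 15 lists and a threshold of 0.05. The smallest p these lists can give is 0.0001. Being one-sided, it does not test whether a list with a fold below 1 has fewer genes near peaks than random lists. The Benjamini-Hochberg adjustment was made separately under each rule for giving peaks to genes. It does not cover the choice among rules. The intervals of a list's fold are those of its share divided by the random mean. All 338 symbols of the lists matched the table, 1 of them through an older symbol, giving 313 distinct genes. The lists cover regulators of stem and progenitor cells, B, T, NK, granulocyte and monocyte, megakaryocyte and erythroid, mast cell and dendritic cell genes, circadian and PAR bZIP genes, liver targets of PAR bZIP proteins, apoptosis, cell cycle, cytokine receptors, and liver and neuronal controls.

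The lists, the list tests and most alternatives were fixed before the data were examined. The boundary test took the place of the planned promoter test because the gene table gives no strand. Exon, intron, UTR and intergenic classes had been planned, and the comparison of gene bodies took their place once the gene table had been seen. The tests on chromosome X and on clusters of peaks were chosen after seeing the data. The rule for named genes took up to 5 members per list with the highest-ranked peaks, together with Hlf. Since the file holds no rank, members with the most peaks and then with the peak nearest a gene boundary were taken, a choice made after the data were seen. Further members are named where a count of list genes near peaks is spelled out or where members without a peak are listed, and these were also chosen after their values were seen. One list member's own result is not reported here. The rule's 20 peaks with the highest score could not be chosen. Alternatives were other boundary windows, every annotated gene in place of protein-coding genes, peaks within 1 kb merged, other rules for giving peaks to genes and lists without shared genes. Leaving out peaks in Hlf exons or off chromosomes 1 to 19 and X removed no peak.

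On simulated data, 50 peak lists placed at random led to no call of the granulocyte and monocyte list among 21523 genes. The same list was called in 28% of 50 simulations with peaks planted at 4 of its genes and in 100% with 8. Of 700 tests of the other lists without planted peaks, 2 were called. The boundary comparison called 2% of 50 random lists and 100% of those with 100 peaks planted at boundaries. The simulations used fewer random lists and windows than the main tests and placed peaks uniformly. Random placement put 9.93% of protein-coding genes near a peak, against 15.3% for the real list, whose peaks were also clustered. These call rates may therefore not hold for the real list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.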

Results

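HLF (hepatic leukemia factor) is a transcription factor of the PAR bZIP family, which also holds DBP and TEF. The series set out to find where HLF binds in mouse stem and progenitor-enriched cells (Lin-Sca-1+c-Kit+). A FLAG-tagged form was introduced by retrovirus and recovered with an anti-FLAG antibody. The FLAG-HLF library (n = 1) gave 3153 peaks of 400 bp on the mm10 build, together covering 1261200 bp. The list gives no read counts, so the depth is unknown. The empty-vector library (n = 1) was not analysed here. The peaks lay on the 19 autosomes and X, with none on Y or the mitochondrial genome. Neighbouring peaks were a median of 268 kb apart, and the closest pair was separated by 125 bp. The endogenous Hlf gene (gene ID 217082; chromosome 11, 90336535 to 90390917) had no peak in its body or within 20 kb. Its nearest peak was 95.6 kb away.

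The first comparison asked where the peaks lie relative to genes. Peaks were concentrated around the ends of protein-coding genes: 342 of 3153 peak centres, or 10.8% (95% interval 9.78 to 11.98%), lay within 1 kb of a gene boundary, against 3.16% of random windows on the same chromosomes. Examples are Per2 and Tef, a core clock gene and a PAR bZIP paralogue of HLF, with peak centres 93 bp and 145 bp from a boundary. Further examples are Blnk, an adaptor of B cell receptor signalling, at 99 bp, and Nfe2, a megakaryocyte and erythroid transcription factor, at 19 bp. The Nfe2 peak also lay in or within 20 kb of 3 other genes. The odds ratio was 3.73 (3.34 to 4.18; Fisher's exact test, p = 2.05e-84), and none of the 1000 random sets reached a share above 4.19%. Most peaks nevertheless lay farther away. The median distance to a boundary was 14.0 kb for peaks and 46.5 kb for random windows.

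Sequence far from protein-coding genes was under-represented against random windows, which could also fall in assembly gaps or where reads cannot be placed. How much this changes the random shares was not tested. Only 159 peaks, or 5.04% (4.31 to 5.87%), lay outside protein-coding genes and over 100 kb from a boundary, against 26.8% of random windows (odds ratio 0.145, 0.124 to 0.170; Fisher's exact test, p = 9.06e-225). Gene bodies held 1742 peaks, or 55.2% (53.5 to 57.0%), against 41.3% of random windows (odds ratio 1.75, 1.64 to 1.88; Fisher's exact test, p = 8.51e-56). Examples of peaks deep in gene bodies are the 3 in Etv6, at 37.4, 80.1 and 98.0 kb from the nearer gene end, and 1 in Runx1 at 110 kb. Both genes encode haematopoietic transcription factors. The share of peaks in bodies and over 20 kb from a boundary, 22.3% (20.8 to 23.8%), did not differ detectably from the random 23.2% (odds ratio 0.948, 0.872 to 1.03; Fisher's exact test, p = 0.221). Against the same peaks moved 10 kb to each side, an alternative chosen after the data were seen, the odds ratio for gene bodies became 0.956 (0.877 to 1.04), while that for boundaries was 1.94 (1.66 to 2.26).

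**Figure D1:**
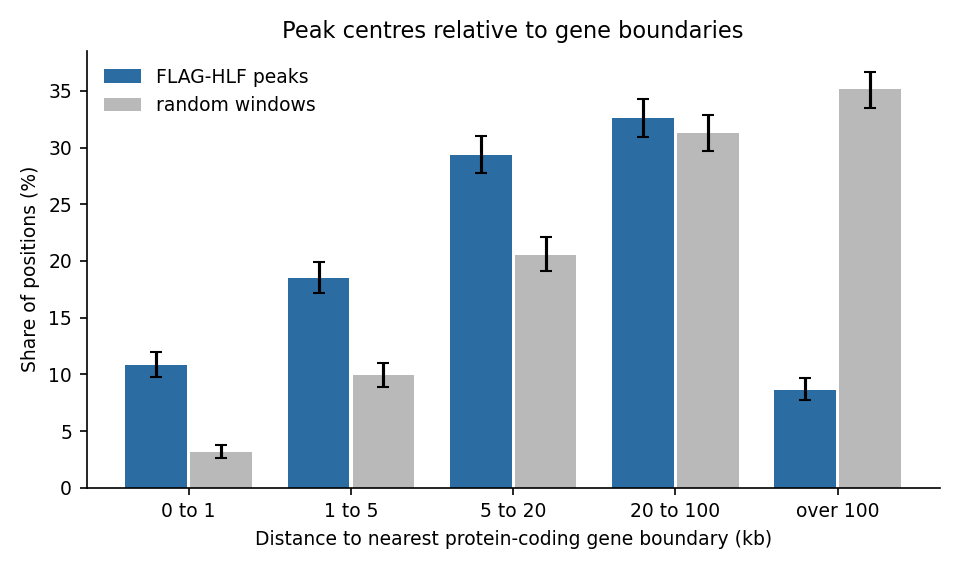
Share of positions (%, y axis) in 5 classes of distance to the nearest protein-coding gene boundary (kb, x axis) for the 3153 FLAG-HLF peaks (blue; bars are exact 95% intervals) and random windows (grey; bars span the middle 95% of 1000 sets). Peaks exceed random windows within 1 kb (10.8% against 3.16%) and fall below them beyond 100 kb (8.66% against 35.1%).

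Peak density differed between chromosomes. The autosomes carried 3128 peaks at 1.30 per Mb of annotated span (1.26 to 1.35). Chromosome 11, where Per1, Mpo, Stat3, Meis1 and Ikzf3 each had a peak in the body or within 20 kb, was the densest per Mb at 2.05 (1.80 to 2.33). Chromosome 19 followed at 1.85 per Mb (1.52 to 2.24). The sparsest autosome per Mb was chromosome 18 at 0.948 (0.755 to 1.18). Scaled by protein-coding gene number in place of span, a scaling chosen after the data were seen, this order of autosomes was lost. Chromosomes 11, 19 and 18 then had 1.001 (0.880 to 1.14), 1.01 (0.826 to 1.22) and 1.07 (0.852 to 1.33) times the peaks expected from the other autosomes, and chromosome 7 was lowest at 0.480 (0.408 to 0.562). Chromosome X held 25 peaks, or 0.149 per Mb (0.0965 to 0.220), where the autosomal density would give 218. The X count is 0.115 times the expected number (0.0741 to 0.169; exact binomial test on the share of span, two-sided, p = 1.84e-59). The test on X was chosen after the data were seen. Among list genes on X, F9, the gene of coagulation factor IX, contained 1 of these peaks.

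**Figure D2:**
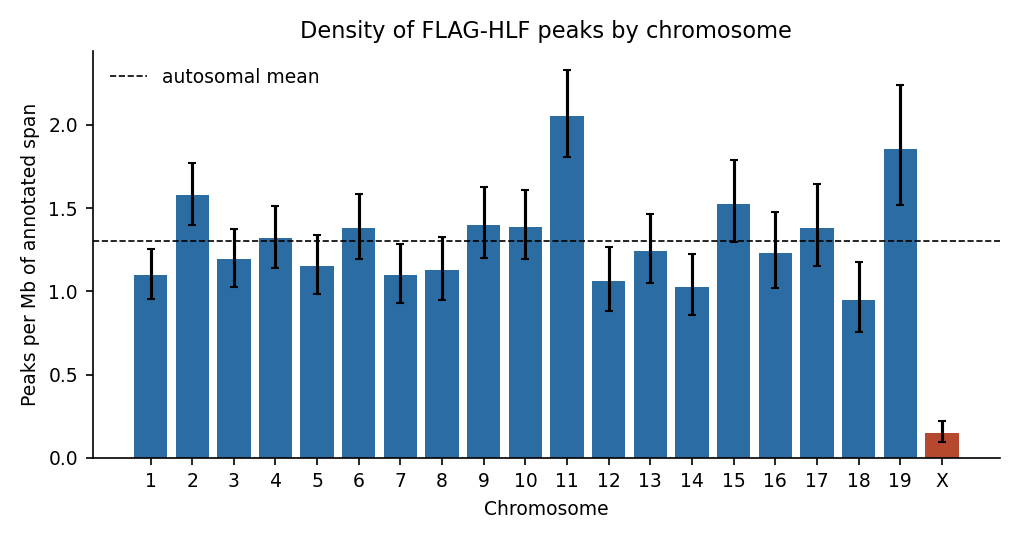
Peaks per Mb of annotated span (y axis) on each chromosome (x axis), with exact Poisson 95% intervals as error bars and the autosomal mean of 1.30 per Mb as a dashed line. Autosomes (blue) range from 0.948 to 2.05 per Mb, and X (red) lies at 0.149 per Mb.

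The next comparison asked which groups of genes lay near peaks. Of 21523 protein-coding genes, 3294, or 15.3% (14.8 to 15.8%), had a peak in the body or within 20 kb. Of the 15 lists, granulocyte and monocyte genes alone passed the test: 12 of 28 members (42.9%, 24.5 to 62.8%) lay near a peak, where random lists of like gene length gave 3.63 on average and 1 to 7 in the middle 95%. The fold over random lists was 3.30 (1.88 to 4.84; permutation p = 0.0002, adjusted p = 0.003). The 12 members were Id1, Itgam, Mpo, Spi1, Prtn3, Cd68, Csf3r, Fcgr2b, Elane, Fos, Cd14 and Lyz2. Spi1 encodes PU.1, the transcription factor of myeloid and B cell development. Mpo, Elane and Prtn3 encode neutrophil granule enzymes, Csf3r the G-CSF receptor, Itgam the integrin CD11b, and Lyz2 lysozyme. Fos and Id1 are not restricted to these cells, encoding an AP-1 subunit and an inhibitor of bHLH factors. Without Fos, Jun and Id1, an alternative added after the data were seen, 10 of 25 members remained (adjusted permutation p = 0.012).

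The 12 genes had 16 distinct peaks, and 3 genes had a peak inside the body. Id1 (chromosome 2, 152736251 to 152737410) had 3 peaks, the nearest centred 9 bp inside a boundary. Of these, 2 also lay within 20 kb of Bcl2l1. Itgam (chromosome 7, 128062640 to 128118491) had 2, at 932 bp inside a boundary and 15.3 kb outside, the latter inside the neighbouring Itgax. Mpo (chromosome 11, 87793784 to 87804412) had 2 outside the gene, at 3.56 and 14.1 kb. Spi1 (chromosome 2, 91082374 to 91115759) had 1 inside at 14.3 kb from the nearer end and 1 outside at 16.5 kb. Prtn3 and Elane are neighbours and shared 1 peak at chromosome 10, 79877753 to 79878152, which lay 1.72 kb from Prtn3 and 8.36 kb from Elane and within 20 kb of other genes too. Cd68, Csf3r and Fcgr2b each had 1 peak outside the gene, at 5.3, 5.6 and 7.1 kb. Fos, Cd14 and Lyz2 each had 1 outside, at 12.1, 16.0 and 19.7 kb. The Cd68 peak was also counted for 8 other genes. The peaks of Mpo, Fcgr2b, Cd14 and Lyz2 and the outer Spi1 peak were counted for 1 or 2 others. Those of Csf3r and Fos and the inner ones of Itgam and Spi1 were counted for no other gene. Genes of the same list with no peak in this region included Cebpa, Cebpb, Cebpe, Irf8, Csf1r, Gfi1, S100a8 and S100a9. The list did not pass the test when a peak had to lie within 5 kb of a boundary (4 members, fold 2.78, adjusted permutation p = 0.279). Nor did it pass within 1 kb (2 members, fold 3.90, 0.459) or in the gene body (3 members, fold 3.18, 0.251). By the nearest boundary within 100 kb it passed narrowly (8 members, fold 2.54, adjusted permutation p = 0.0495).

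Of the circadian clock and PAR bZIP genes, 8 of 23 lay near a peak (fold 1.89, 0.89 to 3.11; adjusted permutation p = 0.233), which did not pass the test at 20 kb. They were Per1 and Per2, which encode repressors of the clock, the nuclear receptor genes Nr1d1, Nr1d2 and Rora, the bZIP genes Tef and Nfil3, and Bhlhe40. Per1 (chromosome 11, 69095108 to 69109965) had 3 peaks, centred 285 bp and 2.22 kb outside one boundary and 3.82 kb inside. Per2 (chromosome 1, 91415977 to 91459351) had 1 peak 93 bp outside a boundary and 1 at 21.6 kb inside. Tef (chromosome 15, 81802673 to 81826863) had 1 at 145 bp outside and 1 at 7.56 kb inside. Nr1d2 (chromosome 14, 18204056 to 18239106) had 1 at 487 bp inside. By the 20 kb rule the Per1 peaks were each also counted for 1 or 2 other genes, and both Tef peaks for 1. Those of Per2 and Nr1d2 were counted for no other gene. With the planned window of 1 kb around boundaries, these 4 genes (Per1, Per2, Tef and Nr1d2) compared with 0.442 in random lists, a fold of 9.05 that passed the test (adjusted permutation p = 0.0165). The neuronal control list also had a high fold at 1 kb without passing, with 2 of 20 members, Grin1 and Snap25 (fold 6.09, 0.752 to 19.3; permutation p = 0.0414, adjusted p = 0.3105), and at 5 kb (3 members, fold 3.00, adjusted permutation p = 0.287). The difference between the circadian and control lists was not tested. The adjusted values cover the 15 lists under each rule and not the choice among rules. The circadian list did not pass within 5 kb of a boundary (5 members, fold 3.91, adjusted permutation p = 0.1095) or in the gene body (6 members, fold 2.71, 0.246), and it passed by the nearest boundary within 100 kb (9 members, fold 2.92, 0.0225). The neuronal controls had a like fold in the gene body (4 of 20 members, fold 2.48, adjusted permutation p = 0.251). By the nearest boundary their fold was 1.13. No peak lay in or within 20 kb of Dbp, Cry1, Cry2, Per3, Clock or Arntl.

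**Figure D3:**
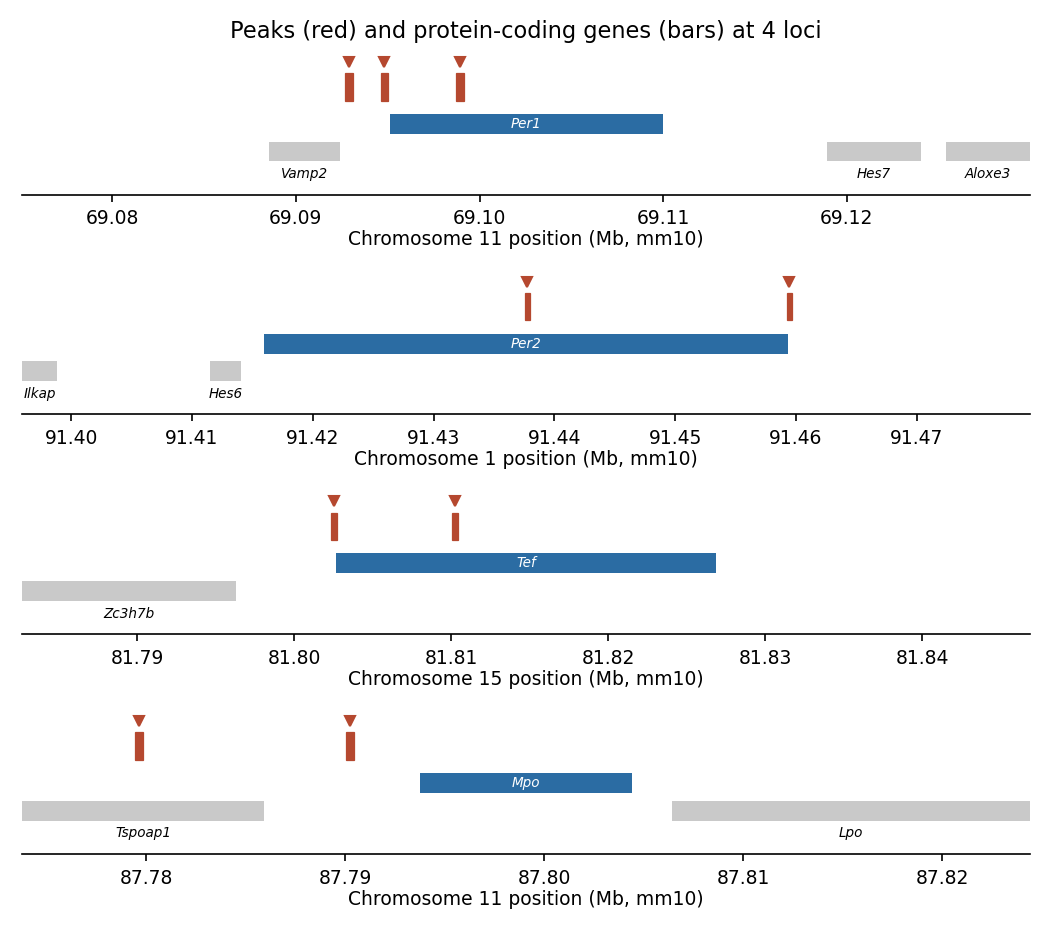
Peaks (red marks with triangles, 400 bp to scale) and protein-coding genes (bars; the named gene blue, neighbours grey, cropped to the window) at Per1, Per2, Tef and Mpo, along mm10 positions in Mb (x axis), each gene with 20 kb on either side. Per1, Per2 and Tef each have a peak within 1 kb of a gene end, and the nearer Mpo peak lies 3.56 kb away.

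Stem and progenitor regulators had 10 of 30 members near peaks (fold 1.72, 0.89 to 2.73; adjusted permutation p = 0.233), which did not pass the test. The 10 were Etv6, Runx1, Lmo2, Zbtb16, Meis1, Egr1, Myb, Cd34, Gfi1b and Erg. Meis1, a homeobox partner of HOX proteins, had 1 peak 654 bp inside a gene boundary (chromosome 11, 19018798 to 19019197). Lmo2, a component of the stem cell transcription factor complex, had 2 peaks at 10.8 and 11.97 kb outside the gene. Runx1 had 2 inside its body, and the single peak at Myb lay 6.00 kb inside the gene. When each peak was given to the gene with the nearest boundary within 100 kb, 11 members were counted and the list passed (fold 2.33, adjusted permutation p = 0.0225). Within 5 kb of a boundary the direction turned, with 1 of 30 members (fold 0.666, adjusted permutation p = 0.840).

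The lymphoid lists did not pass the test. B lineage genes had 7 of 25 members near peaks (fold 1.61, adjusted permutation p = 0.313). These were Flt3 and Foxo1 with 2 peaks each inside the gene, Ikzf3 with 2, and Pax5, Blnk, Bach2 and Spib with 1 each. Ebf1, Il7r, Rag1, Rag2 and Dntt had none. NK and innate lymphoid genes had 6 of 20, among them Zbtb16, Rora and Nfil3 (fold 1.69, adjusted permutation p = 0.313). Nfil3, a bZIP factor required for NK cell development, had 1 peak 5.98 kb inside the gene. T lineage genes had the lowest fold of the 15 lists, with 2 of 25 members, Notch1 and Cd4 (fold 0.446, adjusted permutation p = 0.956). The unadjusted permutation p for as few genes near peaks was 0.146.

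The remaining lists did not pass either. Megakaryocyte and erythroid genes had 4 of 23 members near peaks (Tfrc, Vwf, Nfe2 and Gfi1b; fold 1.29, adjusted permutation p = 0.592). Mast cell, basophil and eosinophil genes had 4 of 16 (Siglecf, Ms4a2, Cpa3 and Ccr3; fold 1.56, 0.529), and dendritic cell genes 4 of 16 (Flt3, Itgax, Cd74 and Spib; fold 1.48, 0.529). Cytokine receptor and JAK-STAT genes had 7 of 26 (fold 1.67, 0.313), among them Ifngr1, an interferon gamma receptor gene, with 3 peaks outside the gene at 0.429, 3.44 and 4.35 kb, and Stat3 with 1 inside and 1 outside at 12.4 kb. Apoptosis genes had 4 of 22 (fold 1.18, 0.605), among them Bmf, encoding a pro-apoptotic BH3-only protein, with 3 peaks within 6.30 kb of a gene boundary, and Bcl2l1, encoding BCL-XL, with 2 at 16.9 and 19.1 kb. Cell cycle genes had 3 of 25 (Cdk6, Cdk4 and Foxo3; fold 0.739, 0.896). Liver targets of PAR bZIP proteins had 3 of 18 (Nr1i3, F9 and Pdxk; fold 1.02, 0.735). The neuronal controls had 4 of 20 (Grin1, Snap25, Neurod1 and Rbfox3; fold 1.26, 0.592), and the liver controls 2 of 20 (G6pc and Apoa2; fold 0.648, 0.896). Nr1i3 and Apoa2 were counted through the same 2 peaks, which lay inside another gene, Fcer1g. They were 13.6 and 14.3 kb from Nr1i3 and 6.06 and 6.8 kb from Apoa2, so they cannot be given to either gene alone.

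**Figure D4:**
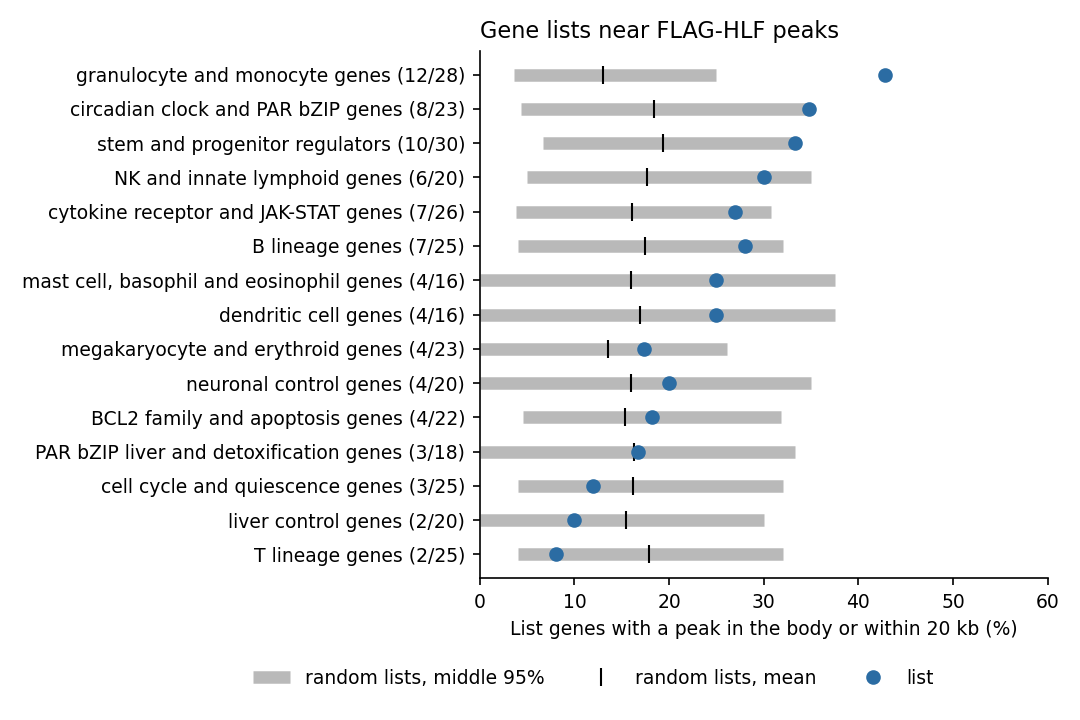
Share of each list's genes with a peak in the body or within 20 kb (%, x axis) for the 15 lists (y axis; genes near peaks over members), with the mean (tick) and middle 95% (grey bar) of 10000 length-matched random lists. The granulocyte and monocyte list, at 42.9%, lies outside its random range, and the other 14 lists lie within or at the edge of theirs.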

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

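The share of peaks near gene boundaries stayed above random under all 6 alternatives, with odds ratios from 1.94 (against peaks moved 10 kb) to 4.68 (window of 500 bp). The share inside gene bodies held with merged peaks and with every annotated gene, but turned to an odds ratio of 0.956 against the moved peaks, where the surroundings of the peaks are the background by construction. The X deficit held throughout, at 0.171 times the number expected from protein-coding gene counts. On that scale chromosomes 11 and 19 went from 1.63 and 1.44 times the expected number to 1.001 and 1.01. Chromosome 18 turned from 0.720 to 1.07, and chromosome 7 went from 0.834 to 0.480. Scaling by gene number in place of span is the cause by construction. In classes of distance to genes, chromosomes 11, 19, 18 and 7 kept their direction, at 1.38, 1.22, 0.792 and 0.684. With peaks given by a window of 5 kb or by the gene body alone, 0 lists passed, although 1 list in each case had an unadjusted permutation p under 0.05, and with the nearest boundary within 100 kb 3 passed. The granulocyte and monocyte list was past the threshold in 6 of its 9 alternatives (adjusted permutation p from 0.0015 to 0.459 over the 9), with a fold of 3.90 at 1 kb, 2.78 at 5 kb and 3.18 in the gene body without passing; fewer members counted under these rules. The circadian list passed at 1 kb (fold 9.05) and by the nearest boundary (2.92), and the stem and progenitor list by the nearest boundary (2.33). None of these calls is adjusted for the choice among rules. Of 121 alternatives for single lists, 99 kept their direction and side of the threshold and 16 crossed a fold of 1, none of them past the threshold on either side. At 1 kb the fold was 0 for the mast cell, dendritic cell, liver target and apoptosis lists and 2.03 for cell cycle genes. At 5 kb it was 0.752 for B lineage, 0.870 for NK, 0.926 for megakaryocyte and erythroid genes, 0.970 for liver targets and 0.666 for stem and progenitor regulators. By the nearest boundary it was 0.911 for megakaryocyte and erythroid genes, 0.889 for liver targets and 1.28 for cell cycle genes. In the gene body it was 0.802 for apoptosis and 1.85 for cell cycle genes, and it was 0.925 for liver targets matched on regional peaks. The cause was not tested for these lists, whose counts were small. The moved peaks, regional match, grouped domains, list without Fos, Jun and Id1, and all alternatives for gene bodies, X, single autosomes and clusters were chosen after seeing the data. Alternatives by peak score, GC content, repeats and motif were not run. No paired analysis was possible because the list comes from 1 library, and no replicate could be left out.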

Other observations

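The analyses of clustered peaks and of line order, the comparison with moved peaks, the comparison of X with single autosomes, the test of X copy number, both tests of the granulocyte list against the other blood lists, and the reading of the pooled blood lists as a part or the whole of the excess were chosen after the results were seen.

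Peaks occurred in clusters. Of windows of 100 kb, 82 held 3 or more peaks, against a mean of 8.61 and a maximum of 20 in 1000 random placements (permutation p = 0.001, the smallest they can give), and 13 held 4 or more against a mean of 0.343. The densest windows, with 5 peaks each, lay on chromosome 11 (87700001 to 87800000), which overlaps Rnf43, Supt4a, Tspoap1 and Mpo, and on chromosome 2 (167300001 to 167400000), which overlaps B4galt5. Windows with 4 peaks included those at Il1a and Il1b, the interleukin 1 genes, at Lcp1, which encodes the leukocyte actin-bundling protein L-plastin, at Trib1, a pseudokinase gene, at Ell2, an elongation factor gene, and at Irf2bp2. The random placements do not follow gene density, and clustering beyond that of genes was not tested. The regions named here were chosen after their values were seen.

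The genes with the most peaks were picked out after their counts were seen. Asph, Gab2, M1ap and Sgms1 each had 5 peaks in the body or within 20 kb, where the autosomal density would give 0.339, 0.348, 0.161 and 0.400. M1ap lies beside other genes. A 100 kb window on chromosome 6 with 4 peaks overlaps M1ap, Dok1, Loxl3, Htra2, Aup1, Dqx1, Tlx2, Pcgf1 and Lbx2. Peaks there cannot be given to M1ap alone. Irf2bp2 and Trib1 each had 4, against 0.0595 and 0.0631, and so did Furin, which encodes a proprotein convertase, against 0.0732. In all, 585 genes had 2 or more peaks and 17 had 4 or more.

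Chromosome X held 0.149 peaks per Mb. The spread between chromosomes argues against chance variation, since the autosomes ranged from 0.948 to 2.05 per Mb. The upper limit for X, 0.220, lies below the lower limit of the sparsest autosome, 0.755. Scaled by gene number, the upper limit for X, 0.252, lies below the lower limit of the lowest autosome, 0.408. These limits treat peaks as independent, and clustering of peaks would make them too narrow. Fewer genes and gene boundaries on the X are also argued against: X had 0.132 times (0.0856 to 0.195) the peaks expected from autosomal densities in classes of distance to genes. A single X copy per cell, as in male animals, would lower X coverage and could remove peaks near a threshold, but this cannot be told apart from other explanations because the list holds 0 peak heights. The labels do not give the animals' sex. Neither filtering of X peaks by the authors nor assembly gaps and unplaceable reads on the X were tested.

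The excess of granulocyte and monocyte genes near peaks was not accounted for by dense peaks in the surrounding region: with random lists also matched on peaks in the surrounding 1 Mb, permutation p was 0.0002. Peaks shared by neighbouring list members were argued against by a permutation p of 0.0001, the smallest the random lists can give, with 1 member kept per group of overlapping domains. The other 7 blood lists pooled had 33 of 141 genes near peaks (fold 1.38, 0.982 to 1.84; permutation p = 0.0289), which is consistent with peaks at blood cell genes in general as part of the excess, though the interval of the fold reaches below 1. Whether this accounts for the whole excess cannot be told apart from a larger share in the granulocyte list, because 2 tests of the difference fell on opposite sides of 0.05. Fisher's exact test, run first, gave p = 0.0586 (odds ratio 2.45), and a permutation within 5 bins of gene length, added afterwards, gave p = 0.00744. Of these, only the permutation takes account of gene length. The length-matched fold intervals, 1.88 to 4.84 for the granulocyte list and 0.982 to 1.84 for the pool, did not overlap. Of the lists outside the pool, circadian and cytokine receptor genes had folds of 1.89 and 1.67. Neuronal controls, apoptosis genes, liver targets, cell cycle genes and liver controls had 1.26, 1.18, 1.02, 0.739 and 0.648. Whether the pooled blood lists differ from these was not tested. No biological explanation was tested, since control peaks were not analysed here.

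Gene-rich surroundings of the peaks were argued against as the whole reason for peaks close to gene boundaries. After moving each peak 10 kb to both sides, 5.92% of positions lay within 1 kb of a boundary against 10.8% of peaks (odds ratio 1.94, 1.66 to 2.26). The moved positions still exceeded the random 3.16%, so a part of the excess is consistent with peaks lying in gene-rich regions. Whether the boundaries are 5′ or 3′ ends was not tested. With control peaks not analysed here, HLF binding at gene ends cannot be told apart from signal present without HLF.

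Line order in the list had no detectable relation to being within 1 kb of a boundary (Spearman rho = -0.0028 across 3153 peaks, adjusted permutation p = 0.877) or in a gene body (0.018, 0.458) and a slight one to chromosome number (0.043, 0.0433), so it was not used as a rank.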
